A study of Mus musculus with 2 samples.

How the data were processed

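DNase-seq was run on adrenal gland tissue of female B6CASTF1/J mice, the first-generation offspring of the inbred strains C57BL/6J and CAST/EiJ, at 2 months of age. The labels call the libraries biological replicates 1 and 2 and number the females and tissue samples separately, but give both the same donor entry. They were treated as 2 replicates of 1 group, and that they are separate mice rests on the numbering alone. DNase I cuts DNA where chromatin is open, and the positions of the cuts are read by sequencing. Each library had its own processed files and none held pooled reads, per the file headers and the labels. The genome build is mm10, per the labels. The aligner and the peak and footprint callers are not given in the sources used here.

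The authors deposited 2 peak lists per library, and the larger was used throughout, with the smaller as a stricter alternative. The threshold that separates the lists is not given in the sources used here. All peaks of the smaller list touched stretches at a false discovery rate of 0.001, against 66.5% and 66.3% of the larger list. The height of each peak is the authors' deposited value, a signal scaled to the library by a rule that is not stated in the sources used here. Heights were whole multiples of a fixed step in each library, 0.00427 in replicate 1 and 0.00889 in replicate 2. Among heights below 200 steps, 100% lay within 0.02 steps of a whole multiple in either library. If 1 step stood for 1 tag scaled to the library total, replicate 1 would hold 2.08 times as many tags as replicate 2. That scaling was not stated, so this ratio was used only as a guide to depth. The deposited p-value and q-value columns of the peak lists held no values, and the summit column was constant, so the midpoint of a peak was used as its centre. The deposited footprints carry a single p-value threshold of 0.01, and the deposited hotspot stretches carry a q-value (false discovery rate) of at most 0.05, per the values in the files. Cuts per base were not analysed here.

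Everything else was computed from these lists. Start sites were those of all transcripts in GENCODE mouse release M21 on GRCm38.p6, the assembly of mm10, and the last peak of every chromosome lay within the reference length. Peaks counted as shared when they overlapped by at least 1 bp, and chance overlap came from peaks moved within their chromosomes 20 times. Correlations used the log10 of the heights over pairs of shared peaks, which are regions and not replicates. A gene counted as having a start-site peak when a peak lay within 1 kb of any of its annotated transcript starts. Its start-site height is that of the tallest such peak in each library, which can lie at an internal start and can be a different peak in each. Peaks around a gene were those within 50 kb of its 5′ end, counted as deposited without merging peaks that overlap. The 5′ end is the outermost annotated position of the gene, which need not be its main promoter. Each of 19 gene lists was set against 10000 random lists of the same size, drawn from 21938 protein-coding genes and matched on decile of the CpG content of the promoter. The percentage of random lists below a list describes these libraries and is not a test over animals. Intervals of shares are exact Clopper-Pearson intervals at 95% and cover counting error only.

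Consensus matches for 22 binding sites were counted on both strands of the 150 bp around each peak's midpoint, and divided by the share in windows outside all hotspots matched on GC content and CpG count. A match was found for 93.7% of the peaks of replicate 1 and 89.6% of those of replicate 2, and enrichment was computed over those. Where the background held fewer than 3 matches, as for REST and HNF1, a count of 3 took its place, so those ratios depend on this choice. For REST, the counts and the ratio without this replacement are given below. Footprints were compared with footprints moved within the same peak, and sharing of footprints with footprints moved among hotspots common to both libraries. Values are given per library or as mean ± SD (SD, n = 2). Because there was 1 group, no test between conditions was possible. The gene lists, consensus sequences, tests and most alternatives were fixed before the data were examined. The alternatives were another start-site window or distance, the stricter or the taller peaks, equal numbers of peaks, unmatched random lists, other motif backgrounds and leaving out each library. Comparisons of peak heights by motif and the sequences of single NR5A sites were chosen after the data were examined.

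Genes named in the text were fixed by rule. A panel of adrenal genes with Alb and Xist is always named, followed by the 2 members of each list with the tallest start-site peaks and up to 2 members without a start-site peak in either library for lists below the housekeeping list. Some genes under this rule are not reported here. Motifs named are the 5 most and 3 least enriched with NR5A and CTCF, and regions are the 5 tallest peaks shared by both libraries. Genes outside this rule were picked after their values were seen, and the text says so. The overlap routine was checked against a direct count. On 20000 simulated windows of replicate 1 with the NR5A consensus planted in 10.38%, the scan found 10.38% above background. In 200 simulated lists without a signal, 0.5% passed the upper bound of the random lists. Work was done in Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9, and sequence alignments with BLAST 2.17.0. The effect of reads from CAST/EiJ alleles on alignment to the C57BL/6J reference was not tested.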

Results

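Chromatin accessibility was mapped by DNase-seq in the adrenal gland of 2-month-old female B6CASTF1/J mice, with 1 library from each of 2 biological replicates. The adrenal gland joins a cortex that makes steroid hormones from cholesterol and a medulla of chromaffin cells that makes catecholamines, and it holds vessels, macrophages, stroma and fat as well. The 2 libraries form a single group with no second condition, so the data describe where chromatin was open in this tissue and how far the replicates matched. Replicate 1 held 204141 peaks and replicate 2 held 146864, with 175502 ± 40501 on average (SD, n = 2). The peaks covered 41.8 Mb and 26.0 Mb of the genome, with median widths of 200 and 175 bp. The authors' stricter lists held 131263 and 94538 peaks, or 112900 ± 25969 (SD, n = 2). Sequencing depth was not stated, and the step between successive peak heights was 2.08 times as large in replicate 2.

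Accessible sites were largely common to both libraries. Of the peaks of replicate 2, 82.7% overlapped a peak of replicate 1, and 58.5% of the peaks of the larger replicate 1 list overlapped a peak of replicate 2. Peaks moved at random within their chromosomes overlapped in 3.14% and 2.25%. When 146864 of the tallest peaks were taken from each library, 73.0% and 74.3% were shared. Heights of 117827 pairs of shared peaks, the authors' values, correlated with a Pearson r of 0.875 on the log10 scale and a Spearman rho of 0.839 across regions, which are not independent replicates. At shared peaks over 1 kb from a start site, Pearson r was 0.780. Identical ends were found for 10338 shared pairs, and the log2 height ratios of the tallest 20% of pairs had an SD of 0.65.

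Steroidogenic genes of the cortex were open at their start sites in both libraries. Of 20 genes on the list, 20 had a start-site peak in replicate 1 and 17 in replicate 2, or 92.5% ± 10.6 (SD, n = 2), and 17 had a peak in both, against a median of 50% in matched random lists. The list lay above 100% of the 10000 random lists matched on promoter CpG content, and above 89.1% of lists drawn without matching. Star, which carries cholesterol into the mitochondrion, had start-site peaks of height 7.83 in replicate 1 and 7.56 in replicate 2, in neighbouring peaks within 1 kb of its 5′ end on chromosome 8 (gene 25806555 to 25815982). Nr5a1, which encodes the steroidogenic transcription factor SF-1, had peaks of mean height 8.06 ± 2.79 (SD, n = 2) on chromosome 2 (gene 38692656 to 38714542). The tallest start-site peaks of the list belonged to Por, the cytochrome P450 reductase, with heights of 23.8 and 24.8 at an internal start but 0.735 and 0.889 within 1 kb of its 5′ end, and Fdxr, the ferredoxin reductase of mitochondrial steroid synthesis, with 18.5 and 23.3.

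Among the enzymes of steroid synthesis, Cyp11b1, which makes corticosterone, had start-site heights of 3.57 and 2.36 on chromosome 15 (gene 74834125 to 74841643). Its neighbour Cyp11b2, the aldosterone synthase of the outer cortex, had a peak of height 0.461 in replicate 1 and none in replicate 2. Hsd3b1 and Mc2r, the receptor for adrenocorticotropic hormone, likewise had peaks in replicate 1 alone, with heights of 0.534 and 0.893. These 3 genes were the members of the steroidogenic list without a start-site peak in replicate 2. Cyp21a1 had heights of 3.54 and 2.13 on chromosome 17, and is uncertain because a near-identical pseudogene lies beside it. Akr1c18, which inactivates progesterone, had heights of 1.33 and 0.951, and Nr0b1, a repressor of SF-1, had 1.05 and 1.17 on chromosome X. Cyp17a1, an enzyme of androgen synthesis, had 2.18 and 0.960 within 1 kb of its 5′ end, and 4.04 at an internal start in replicate 2.

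Cyp11a1, whose product cuts the side chain of cholesterol, had no peak within 1 kb of its 5′ end in either library. Its highest start-site peaks, of height 7.59 and 8.49, lay inside the gene at 58014881 to 58015100 on chromosome 9, in a 5′ untranslated region near the start of another annotated transcript. From the 5′ end at 58006411, the nearest peaks were 2271 bp away in replicate 1 and 2121 bp away in replicate 2. Th, the rate-limiting enzyme of catecholamine synthesis, likewise had its start-site peak at an internal start, at 142899941 to 142900240 on chromosome 7 in replicate 1. No peak lay within 1 kb of its outermost annotated 5′ end, at 142931128, in either library. Which annotated start is the main promoter was not tested for Cyp11a1 or Th, so these absences do not show a closed main promoter.

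Genes of the outer cortex and of cholesterol supply had start-site peaks in nearly every case. For the zona glomerulosa, which makes aldosterone, 11 of 12 genes had a peak in both libraries, more than 97.04% of random lists, with Cyp11b2 the exception. Kcnk3, a potassium channel, had a mean height of 9.19 ± 1.19 (SD, n = 2), and Agtr1a, the angiotensin receptor, had 7.14 and 9.37. The list shares 2 genes with the steroidogenic list. All 21 genes of cholesterol synthesis and uptake had peaks in both libraries, more than 97.1% of random lists, whose median was 90.5%. Dhcr7, the last enzyme of cholesterol synthesis, had heights of 25.5 and 28.2, and Insig1, which holds back sterol synthesis, had 21.1 and 25.4.

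Chromaffin genes of the medulla were also open, at a share inside the range of random lists of like CpG content. Of 22 genes, 21 had a start-site peak in replicate 1 and 20 in replicate 2, or 93.2% ± 3.21 (SD, n = 2). The 20 with a peak in both exceeded 74.3% of matched random lists, whose median was 86.4%, and 98.1% of lists drawn without matching. The vesicular monoamine transporter Slc18a1 had heights of 16.9 and 27.8, and Chgb, a granule protein, had 6.98 and 16.4. Th had 1.00 and 1.13, Dbh had 1.09 and 0.827, and Chga, another granule protein, had 1.52 and 7.66. Pnmt, which turns noradrenaline into adrenaline, had no start-site peak in either library, and the nearest peaks lay 3051 and 3071 bp from its 5′ end.

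Marker genes of supporting cell types differed in how often they were open. All 16 endothelial genes had start-site peaks in both libraries, more than 99.98% of random lists. Flt1 had heights of 3.28 and 7.38, and Esam, a junction protein, had 3.49 and 4.76. In the list for capsule and stroma, 13 of 15 genes had peaks in both, more than 97.8% of matched random lists and 87.5% of lists drawn without matching, and their mean share of 90% fell to 53.3% with the upper 50% of peaks by height. They included Gli1 at 3.45 and 9.49 within 1 kb of its 5′ end and Pdgfra at 5.13 and 11.5 at an internal start, with no peak at Lum. Of 10 adipocyte genes, 9 had peaks in both, more than 97.6% of matched and 84.7% of unmatched random lists, among them Cebpa at 12.9 and 18.2 and Plin1, with 1.58 and 1.16 within 1 kb of its 5′ end and taller internal peaks, of 2.49 and 6.62, at different positions in the 2 libraries. Macrophage genes had peaks in both for 10 of 16, more than 92% of matched random lists but 18.2% of lists drawn without matching, and their mean share of 75% fell to 28.1% with the upper 50% of peaks by height. They included Cd68 at 1.70 and 1.96, Spi1 at 1.53 and 1.92, with no peak at Aif1 or Itgam. Keeping the upper 50% of peaks can only lower a share, and random lists were compared over all peaks only. Schwann and glial genes had peaks in both for 7 of 10, more than 71.6% of matched and 35.7% of unmatched random lists, including Erbb3, at 3.31 and 6.17 in different peaks, but not Cdh19. Lymphocyte genes were below most random lists, with 3 of 11 in both libraries, more than 2.88% of lists. Cd3e, a marker of T cells, had no peak, while Lck had heights of 7.71 and 16.5 and Pax5 had 6.36 and 14.1 at internal transcript starts.

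Genes of other tissues had peaks in both libraries less often than most random lists. Hepatocyte genes had peaks in both libraries for 3 of 15, more than 0.64% of random lists, with no peak at Alb or Ahsg. This list differed between the libraries, with 11 genes with a start-site peak in replicate 1, more than 95.3% of random lists, and 3 in replicate 2, more than 0.46%. The genes with a peak in replicate 1 alone had heights from 0.197 at Cps1 and Hnf4a to 0.931 at Cyp2e1, named here after their values were seen. All but Cyp2e1 lay below 0.568, the median of all peaks of that library. Foxa3, with heights of 12.2 and 15.3 upstream of its 5′ end, and Apoa2, with 3.46 and 4.03, were its tallest. The Apoa2 peaks lay 954 and 974 bp from its 5′ end. Skeletal muscle genes had peaks in both for 6 of 15, more than 1.24% of random lists. Actn3 had 13.6 and 19.1 upstream of its 5′ end, 652 bp away in replicate 2. Ckm had 3.46 and 9.11 in different peaks, and Mb and Myf5 had none. Pancreatic acinar genes had peaks for 2 of 11, more than 0.28% of random lists, with Cela1 at 2.53 and 3.46 within 1 kb of its 5′ end, Rbpjl at 2.30 and 6.55 and none at Cel or Cela2a. Male germ cell genes had peaks for 3 of 10, more than 0.01% of random lists, with Dazl at 11.8 and 14.3, Zpbp at 4.65 and 7.83 and none at Acrv1 or Ddx4. Kidney genes had peaks for 5 of 12, more than 8.32% of random lists. Nphs1 had 0.372 and 1.73 at an internal start, Aqp2 had 0.688 and 1.20, and Cubn and Kap had none.

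Central neuron genes had start-site peaks in both libraries for 9 of 13, more than 7.11% of matched random lists, whose median was 76.9%, and 35.2% of unmatched lists. Slc17a6 had heights of 1.68 and 4.98, and Neurod6 and Slc32a1 had none. Keratinocyte genes had peaks for 4 of 12, more than 17.65% of random lists, with Krt10 at 9.04 and 12.2 at an internal start, Sbsn at 3.47 and 2.68 and none at Dsg3 or Flg2. All 15 housekeeping genes had peaks in both, more than 92.7% of random lists, with Actb at 21.3 and 25.2 and Rplp0 at 20.7 and 26.5. All 16 immediate early and clock genes had peaks in both, more than 86.9% of random lists, with Atf3 at 25.1 and 29.4 at an internal start and the clock repressor Nr1d1 at 25.6 and 27.1. Xist, the RNA that silences 1 X chromosome in females, had 1.74 and 3.24.

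Steroidogenic and chromaffin genes together were more often open than genes of the 6 other tissues. A start-site peak in both libraries was found for 37 of 42 adrenal genes (88.1%) and 27 of 76 genes of liver, muscle, brain, epidermis, pancreas and testis (35.5%). The odds ratio was 13.4 (Fisher's exact test, two-sided, p = 2.50e-08), a test over genes of these libraries and not over animals. This contrast was not matched on CpG content. The odds ratio was 36.9 without replicate 2 and 7.85 with the upper 50% of peaks by height.

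**Figure D1:**
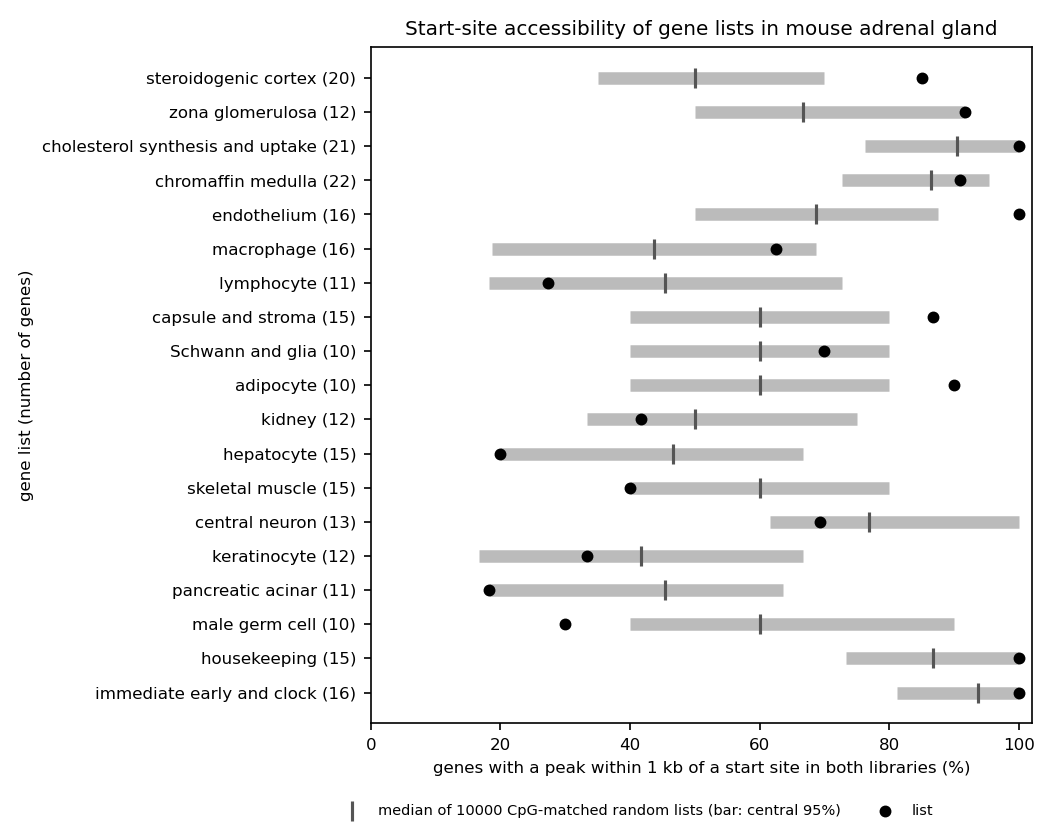
The percentage of genes with a peak within 1 kb of a start site in both libraries is plotted for 19 gene lists as points, with the number of genes in brackets, over bars that span the central 95% of 10000 random lists matched on promoter CpG content, whose median is a tick. Steroidogenic genes lie at 85%, above their bar, chromaffin genes at 90.9%, inside it, and male germ cell genes at 30%, below it.

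Accessible sites were crowded around steroidogenic genes. Within 50 kb of the 5′ end, the median steroidogenic gene had 36.5 peaks in replicate 1 and 17 in replicate 2, or 2.80 ± 0.955 times the median of matched random lists (SD, n = 2). This list exceeded 100% and 99.99% of random lists in replicates 1 and 2. Within 20 kb the ratio was 4.23. Windows of neighbouring list genes, such as Cyp11b1 and Cyp11b2, overlap, so some peaks were counted for several genes. Around chromaffin genes the median was 12 and 8.5 peaks, or 0.815 ± 0.0597 times random lists (SD, n = 2). Immediate early and clock genes had 32.5 and 27.5 peaks, a ratio of 2.32 ± 0.106 (SD, n = 2), and exceeded 100% of random lists in both libraries. Housekeeping genes had 27 and 17 peaks, a ratio of 1.74 ± 0.271 (SD, n = 2) that fell to 1.1 without start-site peaks. Zona glomerulosa genes had 20 and 10 peaks and exceeded 98.6% of random lists in replicate 1 and 49.6% in replicate 2. Ratios of the other 14 lists lay between 0.716 ± 0.104 for keratinocyte genes and 1.52 ± 0.0853 for adipocyte genes (SD, n = 2).

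Around Cyp11a1, 55 peaks of replicate 1 and 22 of replicate 2 lay within 50 kb of the 5′ end, on chromosome 9 in a stretch that also reaches into Sema7a and Ccdc33. Some replicate 1 peaks here overlap each other, such as 58018989 to 58019340 and 58018989 to 58019760, and were counted separately. No replicate 2 peaks here overlap each other, so 55 exceeds the number of separate sites in replicate 1. The tallest peak of replicate 2 in this stretch, of height 9.97, lay at 57965921 to 57966080, between genes, and was also a peak of lower height in replicate 1. A peak inside Cyp11a1, at 58009041 to 58009320 in replicate 1, had heights of 7.40 and 5.94 in the 2 libraries.

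**Figure D2:**
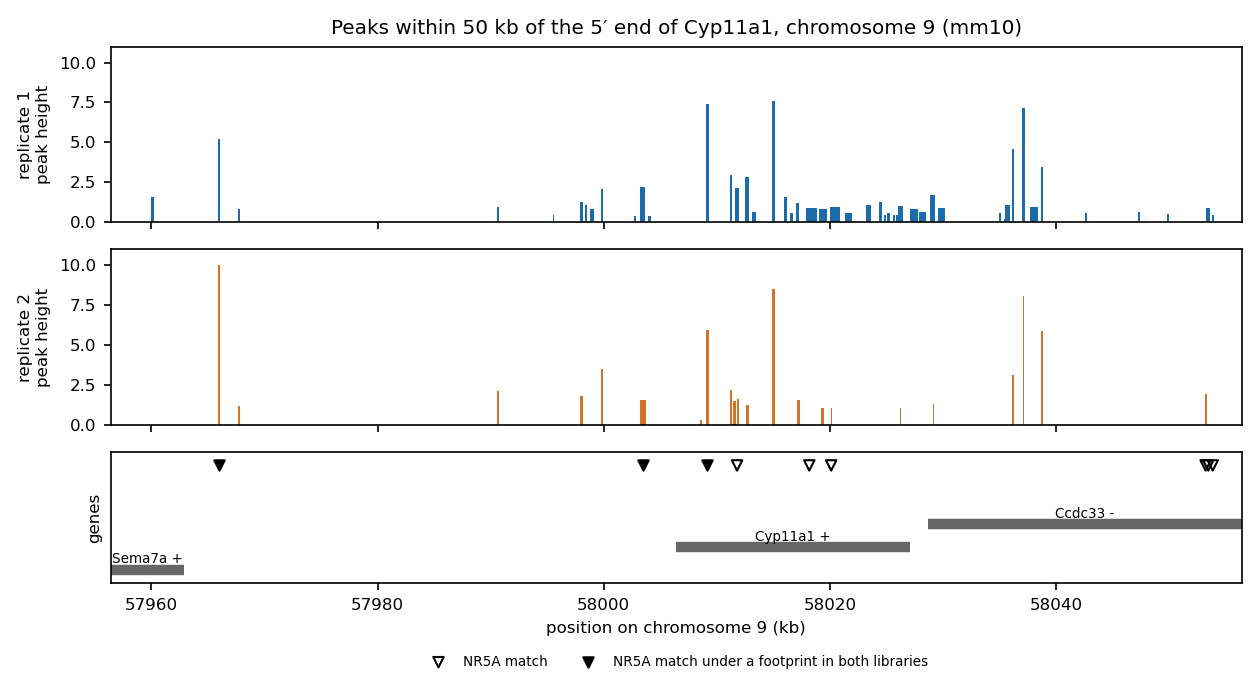
Peaks of each library are drawn at their position (kb) on chromosome 9, mm10, within 50 kb of the 5′ end of Cyp11a1, with the authors' peak height in arbitrary units on the vertical axes, above protein-coding genes with their strand and NR5A consensus matches in peaks. Replicate 1 has 55 peaks and replicate 2 has 22, no peak lies at the left end of Cyp11a1, and 3 of the 9 matches are filled because a footprint covers them in both libraries.

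Across the genome, 72.0% ± 1.48 (SD, n = 2) of protein-coding genes had a start-site peak. Of all peaks, 26.1% ± 4.19 (SD, n = 2) lay within 1 kb of an annotated start, against 6.88% ± 0.0396 for moved peaks. The others fell in introns (37.6% ± 2.93), between genes (31.1% ± 1.22) and in exons (5.11% ± 0.0382; SD, n = 2 for each). Start-site peaks were taller, with median heights of 1.14 and 1.96, than peaks elsewhere, with 0.496 and 0.800. The tallest peak shared by both libraries lay on chromosome 17 at 6430001 to 6430180, 21 bp from a start of Dynlt1b and inside the noncoding gene Gm26848, with heights of 64.5 and 66.5. The next lay in an annotated ribosomal RNA gene at 39846781 to 39846920 on chromosome 17, beside the noncoding gene Gm42418, with 61.3 and 51.9. Hjurp, a chaperone of centromeric histones, had a peak at 88277521 to 88277740 on chromosome 1, in its exon, with 45.3 and 57.3. Nup107, a nuclear pore gene, had a peak at 117792721 to 117792960 on chromosome 10, with 33.3 and 57.2, and the pseudogene 2610005L07Rik had a peak at 20424721 to 20424940 on chromosome 8, with 29.3 and 56.7. Reads at the ribosomal and pseudogene peaks can be shared with other copies, so their heights are uncertain. Whether reads at the other tall peaks, such as that near Dynlt1b, are shared with other sequences was not tested.

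Consensus matches for CTCF, AP-1 and NR5A were enriched in adrenal open chromatin over matched background. The CTCF core, bound by the architectural protein CTCF, was in 3.67% ± 1.01 of peaks, 70.6 ± 18.1 times the share in matched background windows (SD, n = 2). AP-1 sites were in 11.8% and 9.29% of peaks, an enrichment of 5.56 ± 0.613 (SD, n = 2). The NR5A site, which SF-1 can bind, was in 5.95% of peaks in replicate 1 (interval 5.85 to 6.05) and 5.33% in replicate 2 (interval 5.21 to 5.44). Background windows held it in 1.59% and 1.58%, an enrichment of 3.84 ± 0.172 (SD, n = 2). Binding of SF-1 itself was not measured. At peaks over 1 kb from a start site, NR5A sites were in 6.81% and 6.44%, against 3.11% and 2.62% of start-site peaks. The site of REST, a repressor of neuronal genes, was in 126 matched peaks of replicate 1 and no background window, with a counting lower limit of 33.7 for the ratio. In replicate 2 it was in 161 matched peaks and 1 background window, a ratio of 161 with a counting interval from 28.5 to 6398. RFX sites were enriched 5.61 ± 1.26 times (SD, n = 2), from 41 and 34 peaks.

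The least enriched sites were YY1, with a ratio of 0.160 ± 0.00621, SOX, with 0.664 ± 0.00539, and TEAD, with 0.999 ± 0.0528 (SD, n = 2). The direction of YY1 depended on the background, and with flanking windows its ratio was 3.59. With windows of which under 50% is masked as repeats, an alternative added after the data were seen, its ratio was 1.41. TEAD also changed sides, with 1.14 under that alternative, and SOX rose to 0.971 there and to 1.96 against its reversed sequence. With the reversed NR5A and CTCF sequences as the control, their ratios were 14.2 and 824.

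**Figure D3:**
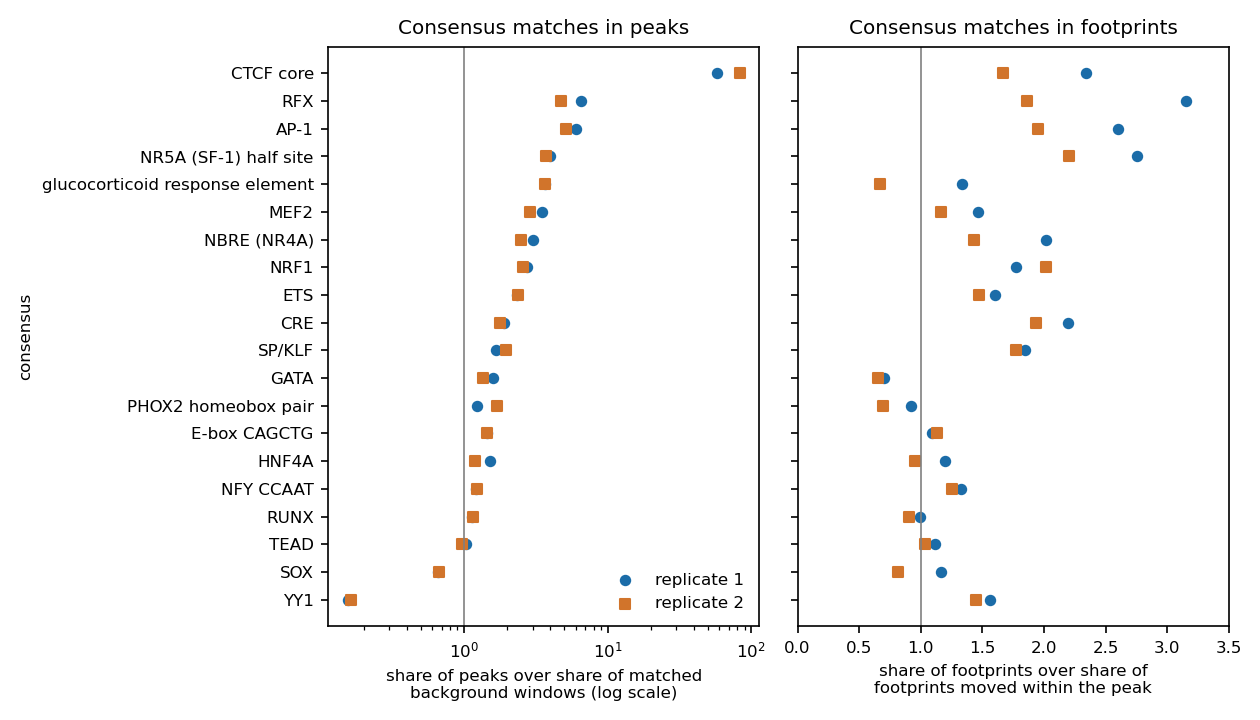
The left panel plots, for 20 consensus sequences and each library, the share of peaks with a match over the share of matched background windows on a log scale, and the right panel plots the share of footprints with a match over that of footprints moved within the same peak. In the left panel CTCF lies farthest right, NR5A at 3.96 and 3.72, and YY1 farthest left, and vertical lines mark equal shares. REST and HNF1 are left out because fewer than 4 background windows held a match.

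Footprints, short stretches protected from cutting inside open chromatin, numbered 452268 in replicate 1 and 317405 in replicate 2, or 384836 ± 95363 (SD, n = 2). At least 1 footprint lay in 76.5% ± 0.846 of peaks (SD, n = 2). Of the footprints, 39.7% and 55.8% overlapped a footprint of the other library. Inside hotspots common to both libraries, 54.4% and 59.6% did, against 20.7% and 22.6% for footprints moved among these hotspots. The share of footprints that overlapped an NR5A site was 2.48 ± 0.390 times that of footprints moved within the same peak. For CTCF sites this ratio was 2.01 ± 0.474 (SD, n = 2). When the whole site had to lie inside the footprint extended by 3 bp, these ratios were 3.79 and 3.94. For GATA sites the ratio was below 1, at 0.676 ± 0.0346 (SD, n = 2). These ratios do not rank how often sites were covered. Counted by site, footprints overlapped 51.5% and 47.8% of NR5A matches in peaks, and 90.6% and 91.7% of CTCF matches.

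NR5A sites were found in peaks around most of the steroidogenic genes examined. None of the 10 genes Nr5a1, Star, Cyp11a1, Hsd3b1, Cyp21a1, Cyp11b1, Cyp11b2, Cyp17a1, Akr1c18 and Nr0b1 had a match in a peak within 1 kb of its 5′ end, where few peaks lay and Cyp11a1 had none, so this absence carries little weight. Within 50 kb, Cyp11a1 had 9 matches in peaks, Cyp17a1 had 6, Star had 3 and Cyp11b1 had none. Footprints of both libraries overlapped, by at least 1 bp, 3 matches around Cyp11a1 and 1 each around Nr5a1, Cyp21a1, Cyp11b2 and Cyp17a1. Over all peaks, footprints overlapped 51.5% of NR5A matches in replicate 1 and 47.8% in replicate 2. A footprint at a match therefore does not set the matches around these genes apart. These sites were chosen after the data were examined. The match nearest to Cyp11a1 with footprints in both libraries lay in an intron of this gene, on the plus strand of chromosome 9 at 58009145 to 58009153, 2734 bp from the 5′ end. The plus strand from 58009130 to 58009168 reads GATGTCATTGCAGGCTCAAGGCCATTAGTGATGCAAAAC. Another lay on the minus strand at 58003500 to 58003508, upstream of Cyp11a1 and outside exons of the noncoding gene Gm17322, 2911 bp from the 5′ end, in peaks of height 2.21 and 1.54. The plus strand from 58003485 to 58003523 reads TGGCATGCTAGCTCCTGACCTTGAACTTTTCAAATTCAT. In Nr5a1 itself, an intronic match at 38705210 to 38705218 on chromosome 2 lay 9332 bp from the 5′ end and was overlapped in part by footprints of both libraries (38705216 to 38705222 and 38705215 to 38705222), inside the plus-strand sequence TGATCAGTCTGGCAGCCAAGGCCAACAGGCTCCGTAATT (38705195 to 38705233). It was in a peak of height 2.95 in replicate 1 and in none of replicate 2.

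Shared peaks with CTCF or REST sites were taller in replicate 2 relative to other shared peaks, and those with AP-1 or NR5A sites were lower. This comparison was chosen after the data were examined. The scaling of heights between libraries is not stated, so log2 ratios of replicate 2 over replicate 1 are read against the median of all shared peaks, 0.30. The median was 2.24 for 132 shared peaks with a REST site, of which 99.2% lay above the overall median, and 1.49 for 5880 with a CTCF site, of which 91.3% did. It was −0.21 for 14336 peaks with an AP-1 site, −0.11 for 1845 with an NBRE, the site of the NR4A receptors, and 0.03 for 7716 with an NR5A site. Peaks found in 1 library alone differed likewise. AP-1 sites were in 12.6% of peaks found in replicate 1 alone and 3.27% of those found in replicate 2 alone. For NR5A sites the shares were 6.02% and 3.48%, and for CTCF 0.378% and 2.30%. With 1 library per replicate and no second group, these differences have no replicate check.

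**Figure D4:**
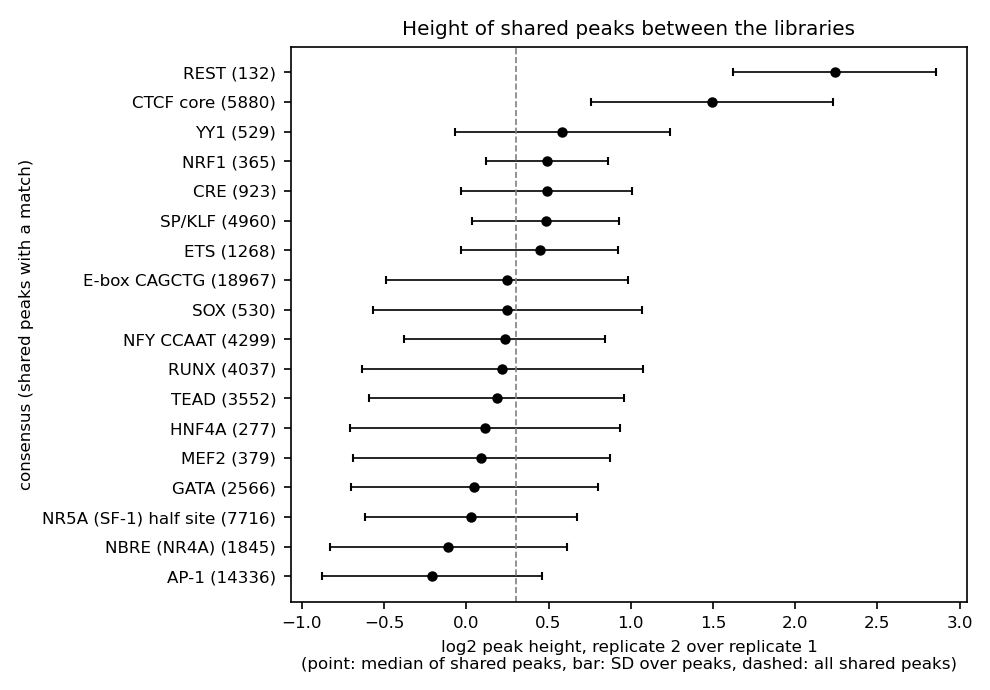
The median log2 ratio of peak height, replicate 2 over replicate 1, is plotted as a point for shared peaks with a match to each consensus, with the number of peaks in brackets and the SD over peaks as a bar. REST peaks lie at 2.24 and CTCF peaks at 1.49, right of the dashed median of all shared peaks at 0.30, and AP-1 peaks lie at −0.21.

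Chromosome X was less densely accessible than the autosomes in these females. It carried 30.8 and 21.7 peaks per Mb, against 80.7 and 58.1 over the autosomes, a ratio of 0.378 ± 0.00586 (SD, n = 2). Autosomes ranged from 64.2 and 44.8 peaks per Mb on chromosome 3 to 117 and 86.3 on chromosome 11. The density of protein-coding genes on X was 0.656 times that of the autosomes. Start-site peaks were found at 56.3% and 52.2% of X-linked and 74.5% and 72.5% of autosomal protein-coding genes. Chromosome Y held 80 peaks in replicate 1 and 35 in replicate 2, or 0.872 and 0.381 per Mb.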

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

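Females carry no chromosome Y, so peaks called there were set apart, and the test below was fixed before its result was seen. Chromosome Y held 80 peaks in replicate 1 and 35 in replicate 2, with median heights of 0.0833 and 0.604 against 0.568 and 0.969 over all peaks.

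Sequence that chromosome Y shares with other chromosomes may account for these peaks. By BLAST, 65 of 80 peaks of replicate 1 (81.3%) and 23 of 35 of replicate 2 (65.7%, exact interval 47.8 to 80.9) aligned elsewhere over at least 90% of their length at 90% identity or more. Of 200 random windows of chromosome Y, 86 did (43.0%, exact interval 36.0 to 50.2). The bounds set beforehand were at least 80% in both libraries for shared sequence and under 50% in both against it, and the interval of replicate 2 spans both bounds, so shared sequence and other sources of Y reads cannot be told apart for these peaks. No biological explanation was tested, since the design has 1 group of females.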

How the results depend on the processing

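The alternatives below were chosen before the data were examined, except 4 added after seeing the data: windows under 50% repeat-masked, equal numbers of top peaks around genes, footprints moved within their own hotspot, and genes whose tallest peaks overlap. Of 491 alternative values, 297 stayed within the spread between replicates or a fixed margin, or on their side of a threshold. Another 121 moved by more and 31 changed sides of 1, and of the added ones 22, 16 and 3 did. Leaving out a library cannot move the mean of both by more than their SD. Such values without a threshold stayed by construction, so this tally does not measure robustness. The 1 left is the start-site height ratio of chromaffin minus steroidogenic genes, which went from 0.43 (p = 0.114) to 0.65 (p = 0.0131, two-sided permutation tests over genes) with overlapping peaks. The Fisher contrast of adrenal with other tissues kept its direction and threshold in all 5 alternatives, with odds ratios from 7.85 to 36.9. Where a value changed below, the cause was not tested unless it is given.

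The stricter peak lists held 112900 peaks on average, and without start-site peaks the height correlation was 0.780. Start-site windows of 500 bp and 2 kb held 20.4% and 33.1% of peaks. Unmatched random lists put the steroidogenic list above 89.1% and the chromaffin list above 98.1% of lists, because matching takes out promoter CpG content. With the upper 50% of peaks, 79.5% of chromaffin genes had a start-site peak, by construction fewer, and mean shares fell from 54.2% to 16.7% for kidney, 46.7% to 23.3% for hepatocyte, 56.7% to 33.3% for skeletal muscle, 76.9% to 50% for central neuron, 27.3% to 18.2% for lymphocyte and 30% to 20% for male germ cell genes. Within 2 kb the share rose from 27.3% to 40.9% for lymphocyte and to 45.5% for pancreatic acinar genes, and unmatched lists put kidney genes above 1.14% and keratinocyte genes above 0.07% of lists. The steroidogenic ratio of peaks around genes was 4.23 within 20 kb and 3.81 without start-site peaks, and the chromaffin ratio was 0.908 within 20 kb, 0.715 within 100 kb and 0.892 without start-site peaks.

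Ratios around other lists crossed 1 in both directions. Kidney gave 0.762 within 20 kb and 0.998 with equal numbers of peaks, and skeletal muscle 0.875 within 20 kb. Without start-site peaks, central neuron gave 1.04, keratinocyte 1.07 and male germ cell 1.22, and male germ cell gave 1.05 within 100 kb. Leaving out each library gave ranges of 0.955 to 1.06 for kidney, 0.917 to 1.33 for skeletal muscle, 0.857 to 1.09 for central neuron, 0.857 to 1.56 for pancreatic acinar and 0.840 to 1.11 for male germ cell.

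NR5A enrichment was 3.40 against flanking windows, 14.2 against its reversed sequence, 4.04 with equal numbers of peaks and 4.42 in windows under 50% repeat-masked, and CTCF was 91.3 against flanks and 824 against its reversed sequence. Against flanks, GATA (0.967), RUNX (0.824), PHOX2 (0.244), HNF1 (0.432) and MEF2 (0.967) fell below 1, and YY1 (3.59) and TEAD (1.18) were above it. Against reversed sequences, CRE (0.767) and ETS (0.397) fell below 1, and YY1 (6.85), SOX (1.96) and TEAD (3.16) were above it. In windows under 50% repeat-masked, YY1 was 1.41 and TEAD 1.14. Repeats cover over 50% of 30.8% and 30.9% of background windows and of 5.69% and 5.78% of peaks. NFY was 0.961 away from start sites, and TEAD lay between 0.962 and 1.04 without either library.

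With the site inside the footprint extended by 3 bp, footprint ratios were 3.79 for NR5A, 3.94 for CTCF, 0.897 for TEAD, 0.902 for HNF4A and 0.773 for MEF2. Leaving out each library gave 0.813 to 1.16 for SOX, 0.952 to 1.20 for HNF4A. For HNF1, which no footprint of replicate 2 overlapped, the ratio was 0 without replicate 1 and 1.5 without replicate 2. By covered bases, the X ratio was 0.362. No paired analysis was possible because there is 1 group. Cleavage at motif matches, a correlation over the union of peaks and a stricter footprint threshold were not run, since cuts per base were not used here and footprints carry a single threshold. If height steps count tags, replicate 1 rests on 2.08 times as many tags as replicate 2, which limits what the missing start-site peaks of Cyp11b2, Hsd3b1 and Mc2r in replicate 2 can show.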

Other observations

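The patterns below were picked from the results, and the bounds of the depth, medulla, top-peak and NR5A tests were written before those tests were run. The test of REST sites, the comparison over overlapping peaks and the comparison without genes that have a REST site were chosen after related values were seen. So were, from here on, all genes outside the naming rule and all lists other than the steroidogenic and chromaffin lists. Among 21938 protein-coding genes, the 8 with the most peaks within 50 kb, by the mean of the 2 libraries, were all in the Hoxb cluster on chromosome 11. This cluster encodes transcription factors of body patterning. Hoxb5 (96303336 to 96306121) had 124 peaks in replicate 1 and 100 in replicate 2, Hoxb6 had 114 and 93, Hoxb4 had 107 and 95, and Hoxb2 had 72 and 68. In replicate 1 alone, genes outside the cluster exceeded Hoxb2, such as Cbarp with 82 and Atp5d with 81 on chromosome 10. The windows of the Hoxb genes overlap, so these genes count many of the same peaks.

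With equal numbers of top peaks from each library, the genes with the greatest excess of peaks in replicate 1 were Bcar1, with 48 peaks against 16, and Cyp11a1, with 54 against 22. Ppara, a regulator of fatty acid breakdown, followed with 50 against 19, then Amotl2 with 49 against 19. H6pd, which supplies NADPH to the enzyme that regenerates glucocorticoids, had 53 against 24. Peaks that overlap within a library were counted separately, as around Cyp11a1 in replicate 1. The greatest excess in replicate 2 was at Traf3ip1, with 20 against 44, and at Cptp, Ints11 and Tas1r3, neighbours on chromosome 4 with 21 against 44 each, though over all peaks these 3 had 42 against 44. Over genes whose tallest peaks overlap between the libraries, start sites of cholesterol genes had a mean log2 height ratio, replicate 2 over replicate 1, of 0.24 ± 0.40 (SD, n = 20 genes), above 1.14% of random lists, and housekeeping genes had 0.26 ± 0.23 (SD, n = 13 genes), above 3.85%.

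Greater depth of replicate 1 may account for its larger number of peaks. Peaks found in replicate 1 alone had a median height of 0.325, between the lower quartile of 0.316 and the median of 0.568 of that library, and 6.22% of the peaks of replicate 2 were absent from replicate 1 yet above its median height. The bounds set beforehand for depth were a median below the lower quartile and under 1%. The bound against it was a median at or above 0.568. The 6.22% sets heights of replicate 2, whose median is 0.969, against that of replicate 1, though the scaling between them is not stated. It carries little weight for that reason. Read within replicate 1, the median of 0.325 met neither its bound for depth nor the bound against it. Depth and other differences between the libraries cannot be told apart for the whole set of peaks. Around steroidogenic genes, fewer calls in replicate 2 are unlikely as the whole cause, since with equal numbers of top peaks the median gene had 33 peaks in replicate 1 and 17 in replicate 2, a ratio of 1.94 that exceeded 100% of random lists and their upper bound of 1.33. That ratio also passed its upper bound around pancreatic acinar (1.83), zona glomerulosa (1.65) and housekeeping genes (1.47), so the excess is not particular to steroidogenic genes, and a difference between the samples or their dissections stays open as untested, with no second group in the design. Peaks that overlap within a library were counted separately here too, and their part in these ratios was not tested.

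The height ratio of replicate 2 over replicate 1 was higher at start sites of chromaffin than of steroidogenic genes, with mean log2 ratios of 0.57 ± 1.01 (SD, n = 20 genes), above 76.5% of random lists, and 0.14 ± 0.42 (SD, n = 17 genes), above 0.81%, a difference of 0.43 (SE 0.25, two-sided permutation test over genes, p = 0.114). Some of these ratios set different peaks against each other, and over genes whose tallest peaks overlap the means were 0.79 ± 0.85 (SD, n = 16 genes), above 99.1% of random lists, and 0.14 ± 0.44 (SD, n = 15 genes), above 1.44%, a difference of 0.65 (SE 0.24, two-sided permutation test over genes, p = 0.0131). A larger share of medulla in replicate 2 might give this, but central neuron genes were also high, at 1.04 ± 0.47 (SD, n = 7 genes), and the 16 chromaffin genes ranged from −0.40 at Dbh to 2.33 at Chga, or from −2.04 at Gata3 over all 20. By the bounds set beforehand 0.43, within 0.5 of 0, speaks against a medulla share and 0.65 would speak for it, and a margin of 1 SE, asked for after the first value was seen, leaves 0.43 undecided, so medulla share and other differences between the libraries cannot be told apart for these genes. Taller REST sites in replicate 2 are a candidate source of part of the higher chromaffin ratio. Shared peaks with a REST match had a median log2 ratio 1.94 above shared peaks without. Chga, Chgb and Snap25 are the chromaffin genes with a match near the 5′ end. Without them the difference was 0.21, or 0.41 over overlapping peaks. Scg2 (2.05) and Cartpt (1.93) were as high without a match. None of the 9 central neuron genes with peaks in both libraries had a match near its 5′ end. Only exact matches to a single consensus were scanned. Of protein-coding genes with start-site peaks in both libraries, 24 had a match and 15319 had none. A gene without a match may therefore still hold a REST site, and these genes do not decide the question.

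It was also asked whether NR5A sites are more frequent in peaks around steroidogenic than around chromaffin genes. Within 50 kb, 45 of 610 peaks around steroidogenic genes had a site in replicate 1 (7.38%) and 18 of 260 around chromaffin genes (6.92%). In replicate 2 the counts were 29 of 341 (8.50%) and 14 of 187 (7.49%). The share was higher around steroidogenic genes in both libraries, but neither difference passed Fisher's exact test, two-sided (p = 0.887 and p = 0.742), over peaks of these libraries. With these counts, a difference of this size cannot be told apart from none.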
